A study of Mus musculus with 12 samples.

How the data were processed

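The series holds RNA-seq libraries of the cerebral cortex from mice aged 8 weeks, 6 with loxP-flanked Nsd1 and Nestin-Cre and 6 with loxP-flanked Nsd1 and no Cre. The labels number them as biological replicates without naming animals, so p-values measure the spread between these 12 samples. Per the labels' protocols, libraries were made from 250 ng of total RNA after ribosomal RNA depletion, with a directional kit. The submitters' processing notes name Trim Galore, Bowtie, STAR, bedtools and the mouse build mm9, without versions or roles. Whether counting used the strand is not given in the sources used here, so a gene and its antisense partner may share reads. Reads from near-identical genes may be divided between them in the same way.

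The deposited table holds 34193 rows with a gene name each and 1 column per library. Its values are, per the file headers, counts normalised by the authors with DESeq2, a signal in units of reads scaled between libraries. Every deposited signal above 0 was a whole multiple of a single step per library within a tolerance of 0.01 reads (100% of values), and dividing by that step gave whole reads. The same table holds the authors' own DESeq2 comparison: a log2 fold change with its standard error, a score for each gene (the Wald statistic) and a p-value with its adjusted p-value, all as deposited by the authors. Names resembling dates, as a spreadsheet makes from certain gene symbols, stood in 25 rows, which were kept under those names.

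The columns are named by genotype and number. Y-linked reads (Ddx3y, Eif2s3y, Kdm5d and Uty, above a summed value of 100) were found in columns 1 to 3 of each genotype and not in columns 4 to 6, which disagrees with the sex label of the same-numbered sample in 8 of 12 columns. The labels also give 3 males and 3 females per genotype. Columns were therefore assigned to their genotype only, and not to single samples. The planned model had genotype and sex. A DESeq2 fit with genotype and a term for columns with or without Y-linked reads gave the authors' deposited log2 fold changes within 9.2e-09, whereas genotype alone differed by up to 1.36 and the labelled sex of the same numbers by up to 1.22. The sex term of the model was for this reason taken as the split by Y-linked reads, a choice made after the values had been seen. The libraries of the split are described by their reads and not as labelled males and females.

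The main test was limma with an intensity trend on log2(value + 1), two-sided, with genotype and the Y-linked term, for 14397 genes with a mean of at least 10 normalised reads over the 12 libraries. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate the change of weakly expressed genes. Effects within each set of libraries and their difference came from a model of 4 genotype-by-set groups. Intervals for shares of reads are not printed because each rests on at least 10.5 M reads, and counting error is small beside the differences between libraries. Pairs of replicates differed by far more than sampling noise (chi-square per degree of freedom from 7.03 to 169 over 30 pairs), so no pair was treated as a repeat of 1 library.

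Before the data were examined, 27 gene lists and the naming rule were fixed. The lists covered methylation machinery, Polycomb, Hox, protocadherin, germline and imprinted genes, neuronal, glial, vascular and neighbouring-region markers, synaptic, channel, guidance and immediate early genes, stress and interferon responses, ribosomal proteins, progenitors, overgrowth genes and growth factor signalling. The rule named Nsd1, the 10 largest changes in each direction among called genes with a mean of at least 50 and a symbol that is not a predicted model, up to 2 called members of each list, marker genes of the sexes, Nes and Gh. Nes and Gh were chosen for the Nestin-Cre transgene, but their values are those of the mouse genes and do not measure the construct. Gh was below the filter and is not tested here. Lists with at least 5 tested members were tested by camera with a preset correlation of 0.01, camera with an estimated correlation, fry, and an exact permutation of the 12 libraries. The smallest p this permutation can give is 0.00216.

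Gene spans were taken from the RefSeq table of assembly GRCm38 and transcript lengths from GENCODE annotation of the same assembly, matched by symbol or unique synonym, for 97.9% and 98.2% of tested genes. As the submitters' notes name another build, coordinates are not printed. Alternatives were the pseudocount, the filter, scaling by TMM or quantiles, array weights, edgeR and DESeq2 on the recovered reads, no sex term, a block for the column number and leaving out each library. Added after the data had been seen were a fit without control libraries 4 and 5, edgeR on reads thinned to equal numbers outside mitochondrial ribosomal RNA, and removal of a linear trend of each library with log2 transcript length. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0.

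The procedures were tested on simulated counts with 200 changed genes, drawn independently for each gene. Deviations that the real libraries share across genes were absent from these counts, so the rates do not cover them. In the main comparison, over 14397 genes, 64.2% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 98.5% of those changed 3-fold were recovered, with 5 false calls among 173, and data without changes gave 0 calls.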

Results

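Total RNA from the cerebral cortex of 8-week-old mice was sequenced after removal of ribosomal RNA. The conditional knockout (cKO) mice carried loxP-flanked Nsd1 alleles and a Nestin-Cre transgene, which drives recombination in the neural lineage. Controls carried the same Nsd1 alleles without Cre. NSD1 is a methyltransferase for lysine 36 of histone H3, and the series title places it in the patterning of DNA methylation outside CG sites in neurons. Each group had 6 libraries, which the labels describe as biological replicates. Reads assigned to genes, recovered from the deposited values, numbered 10.5 to 21.1 M in the controls and 14.6 to 27.0 M in the cKO (exact permutation test of the totals, two-sided, p = 0.167). A value that stands for 3 reads lay between 1.98 and 5.64 normalised reads, depending on the library. Libraries are numbered as in the deposited table. In each genotype, libraries 1 to 3 passed a summed value of 100 for 4 Y-linked genes and libraries 4 to 6 did not. The latter are described as without Y-linked reads, although cKO library 6 held Ddx3y, Kdm5d and Uty at 1.03 normalised reads each. Mitochondrial ribosomal RNA took 14.2% of the reads in control library 4 and 11.5% in control library 5, and 1.46% to 6.00% in the other 10 libraries.

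Nsd1 was measured first, as the targeted gene. Its level was 4235 ± 850 normalised reads in the controls and 3251 ± 299 in the cKO (SD, n = 6 each), a ratio of 0.768. The log2 fold change of -0.36 (SE 0.12) did not pass limma's threshold over all tested genes (adjusted p = 0.383). Taken alone, as the gene fixed in advance, it had a 95% interval of -0.62 to -0.10 (limma, unadjusted p = 0.0099). The authors' deposited table gives Nsd1 a log2 fold change of -0.38, with a standard error of 0.13 and an adjusted p of 0.216. Control libraries 3 and 6, at 3214 and 3257 normalised reads, lay inside the cKO range of 2853 to 3617. The 2 sets of libraries gave log2 fold changes of -0.44 with Y-linked reads and -0.28 without them. After a linear trend with transcript length was removed from each library, a setting added after the data had been seen, Nsd1 fell by 0.49 on the log2 scale (SE 0.08, limma adjusted p = 0.0041). The values cover the whole gene, and the labels do not say which part of Nsd1 is flanked by loxP sites, so reads from outside the deleted part are included and the value does not measure the extent of recombination. Nes, the mouse gene of nestin, stood at 238 ± 66.3 normalised reads in the controls and 279 ± 71.1 in the cKO (SD, n = 6 each, limma adjusted p = 0.612).

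The comparison of cKO with control cortex asks which genes differ in mice that carry Cre beside the loxP-flanked Nsd1 alleles. Casp1, Kank4 and Esam were among the genes that rose, and Ighm and Crlf2 among those that fell. Of 14397 genes tested, 120 changed (limma, adjusted p under 0.05), and 110 of these, or 91.7%, rose in the cKO while 10 fell. The genes that rose did so by a median ratio of 2.14, and 71 of the 110 had a mean below 100 normalised reads over the 12 libraries, against a median of 396 for all tested genes. For 93 of the 110, each cKO library lay above each control library, and for all 10 genes that fell, each cKO library lay below each control. Such complete separation was found for 1.01% of all tested genes, against 0.216% by chance. An unadjusted p under 0.05 was found for 1401 genes, where a share of 0.05 of the tested genes is expected without any change. The authors' deposited table lists 178 genes at an adjusted p under 0.05, with 154 higher and 24 lower in the cKO, and includes all 120 genes called here. edgeR on the recovered reads called 119 genes.

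Among the 10 genes that rose most under the naming rule, Casp1, the inflammatory caspase that processes interleukin precursors, increased from 37.2 ± 12.2 to 152 ± 34.5 normalised reads (SD, n = 6 each), a log2 fold change of 2.03 (SE 0.18, limma adjusted p = 1.4e-05). Kank4 rose from 105 ± 17.1 to 330 ± 23.6 normalised reads and Esam, an adhesion molecule of endothelial junctions, from 217 ± 22.1 to 530 ± 50.8. Both had a limma adjusted p of 8.9e-07. Subunits of ion channels were among the others. Chrnb3, a nicotinic acetylcholine receptor subunit, rose by 1.58 on the log2 scale, and Scnn1a, the alpha subunit of the epithelial sodium channel, by 1.47. Rec8, a cohesin subunit of meiotic chromosomes, rose by 1.61, Grid2ip, a protein that binds the glutamate receptor GluD2, by 1.43, and Evpl, a component of the cornified envelope of epithelia, by 1.38. Cpxm2 rose by 1.32 and Eps8l2, a regulator of actin filaments, by 1.30. All 10 kept a limma adjusted p of at most 0.00164 whichever single library was left out. The 2 largest changes, named after their values were seen, were those of Tekt2, a tektin of cilia and flagella, which rose from 3.54 ± 1.89 to 42.1 ± 9.51 normalised reads (SD, n = 6 each), and of Ces5a, a carboxylesterase, with a log2 fold change of 3.08 (SE 0.20). Ces5a belongs to a family of similar genes among which reads can be shared.

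**Figure D1:**
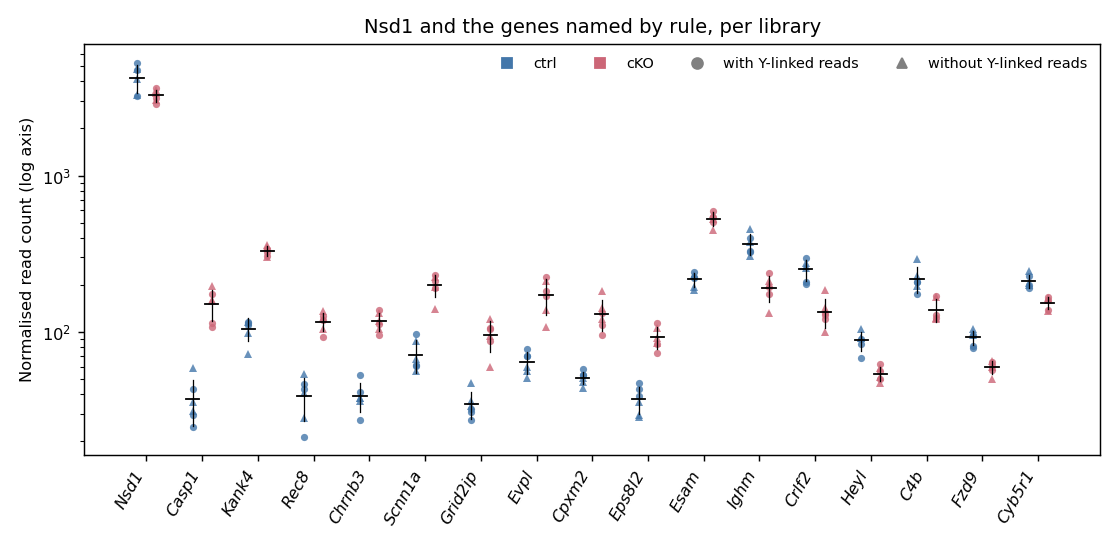
Normalised read counts of Nsd1 and of the 16 other genes named by rule as the largest changes, on a log axis. Each point is a library, horizontal bars are group means and vertical bars are ±1 SD (n = 6). The cKO libraries lie above all controls for the 10 genes from Casp1 to Esam and below all controls for the 6 genes from Ighm to Cyb5r1, whereas the groups overlap for Nsd1.

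Only 6 genes met the naming rule among those that fell. Ighm, the immunoglobulin mu heavy chain, fell from 365 ± 56.2 to 191 ± 35.6 normalised reads (SD, n = 6 each), a log2 fold change of -0.94 (SE 0.14, limma adjusted p = 0.00153). Crlf2, a cytokine receptor chain, fell by 0.90 on the log2 scale, Heyl, a Notch target, by 0.69, C4b, a complement component, by 0.65, Fzd9, a Wnt receptor, by 0.62, and Cyb5r1 by 0.45. The other 4 genes that fell, named after their values were seen, were Trim71 (log2 fold change -2.26), Ighg2c (-1.49), Prtg (-1.02) and Pmaip1 (-0.98). Trim71 stood at 21.8 ± 4.99 normalised reads in the controls and 4.02 ± 2.01 in the cKO (SD, n = 6 each). The cKO level was near the value of 3 reads. Ighm and Ighg2c come from the immunoglobulin heavy chain locus, whose similar segments can share reads, and the same holds for C4b and its near copy. C4b lost its limma call without control library 1, 3, 4 or 5 or cKO library 1, 2, 4 or 6 (adjusted p up to 0.0762), and Cyb5r1 without any single library except control 2 and cKO 3 (up to 0.122). Without both control libraries 4 and 5 the limma calls of Heyl (adjusted p = 0.0921), C4b (0.232), Fzd9 (0.0996), Cyb5r1 (0.0836) and Prtg (0.0709) ended, with log2 fold changes of -0.67, -0.51, -0.60, -0.51 and -0.94 from fewer libraries. With edgeR on reads thinned to equal numbers outside mitochondrial ribosomal RNA, Heyl (adjusted p = 0.127), Fzd9 (0.0993), Cyb5r1 (0.0698) and Pmaip1 (0.266) were not called, with log2 fold changes of -0.70, -0.66, -0.55 and -0.95.

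**Figure D2:**
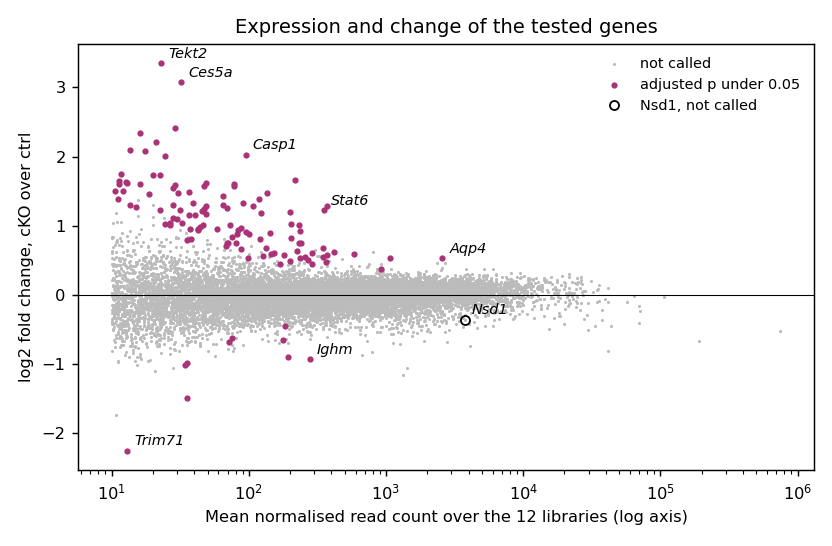
Log2 fold change of the cKO over the controls against the mean normalised read count over the 12 libraries, on a log axis, for the 14397 tested genes. Coloured points are the 120 genes with a limma adjusted p under 0.05, of which 110 lie above 0, and the open circle marks Nsd1.

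Gene lists fixed before the data were examined were then compared, to ask whether chromatin regulators, neuronal classes or signalling genes moved as groups. The 35 tested members of the H3K36 and DNA methylation machinery had a median log2 fold change of 0.01, the 30 Polycomb subunits 0.01 (mean -0.0031), the 42 imprinted genes 0.04 (mean -0.00082) and the 25 overgrowth and intellectual disability genes 0.05. None of these 4 lists had a member called over all genes. Adjusted over the list alone, Cdkn1c, an imprinted inhibitor of the cell cycle, was called with a log2 fold change of -0.52 (limma adjusted p = 0.0273 over the list and 0.0689 over all genes). No Hox gene reached the expression filter. Camera with its preset correlation of 0.01 called 7 of the 26 lists tested, 6 higher and 1 lower. No list was called with an estimated correlation, by fry as a shift in a common direction, or by an exact permutation of the libraries after adjustment, where the smallest adjusted p was 0.281. As this permutation cannot give a p below 0.00216, a list standing alone among 26 could not pass the adjustment. Its lack of calls therefore does not decide on single lists. The smallest exact permutation p before adjustment was 0.0108, for germline genes. Tested by fry for change in either direction, 3 lists were called: germline genes (adjusted p = 0.0026), hippocampus (0.0026) and upper-layer neurons (0.0032), each of which holds a called gene described here, Rec8, Lct and Scnn1a. Of 26 lists, 2 had an unadjusted exact permutation p under 0.05.

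The 24 tested clustered protocadherins, neuronal adhesion molecules from a gene cluster, had a median log2 fold change of 0.24, with 22 of 24 above 0 (camera adjusted p = 9.4e-06). The adjusted p was 0.733 with an estimated correlation, no member was called over all genes or adjusted over the list alone, and reads can be shared between these similar genes. The 7 tested germline genes had a median of 0.13 (camera adjusted p = 0.0305, and adjusted p = 0.598 with an estimated correlation), and Rec8 alone was called, over all genes and adjusted over the list alone. That median was 0.05 without control library 1 and 0.52 without cKO library 6. Immediate early genes, the transcription factors and effectors induced by neuronal activity, had a median of 0.18 over 28 members (camera adjusted p = 0.00337, and adjusted p = 0.819 with an estimated correlation). The unfolded protein and heat shock list had a median of 0.20 over 24 members (camera adjusted p = 0.00102, and adjusted p = 0.733 with an estimated correlation). Insulin-like growth factor and MAP kinase genes had a median of 0.11 over 35 members (camera adjusted p = 0.00491, and adjusted p = 0.733 with an estimated correlation). Among these, Dusp4, a phosphatase of MAP kinases, was called adjusted over the list alone (log2 fold change 0.65, limma adjusted p = 0.0402, and 0.105 over all genes). Axon guidance and cell adhesion genes had a median of 0.09 over 63 members (camera adjusted p = 0.0305, and adjusted p = 0.943 with an estimated correlation). In the immediate early, unfolded protein, insulin-like growth factor and axon guidance lists no member was called over all genes. The differences of the mean log2 values among the libraries with and without Y-linked reads were -0.01 and 0.30 for the unfolded protein list, 0.10 and 0.32 for clustered protocadherins, 0.02 and 0.12 for axon guidance and 0.07 and 0.14 for insulin-like growth factor genes. They were 0.53 and 0.30 for germline and 0.16 and 0.13 for immediate early genes, and the sets were not tested against each other. Without control libraries 4 and 5, camera gave adjusted p of 0.0527 for the immediate early, 0.158 for the unfolded protein and 0.140 for the axon guidance list, whose medians were then 0.11, 0.08 and 0.06. The camera call of the immediate early list also ended without control library 1 (adjusted p = 0.0740), that of the germline list without control library 1 or 2 or cKO library 1 or 4 (up to 0.0848), and that of the axon guidance list without control library 3, 5 or 6 or cKO library 2 or 5 (up to 0.737). The calls of the insulin-like growth factor and unfolded protein lists held without any single library, with medians down to 0.07 (without cKO library 5) and 0.13 (without cKO library 4). The median of the axon guidance list was 0.03 without control library 3, and 0.02 with the transcript length trend removed, a setting added after the data were seen, where camera did not call it (adjusted p = 0.662).

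Cytosolic ribosomal protein genes had a median log2 fold change of -0.38, and 43 of 43 lay below 0 (camera adjusted p = 1.8e-13, and adjusted p = 0.733 with an estimated correlation). No member was called, over all genes or adjusted over the list alone, and the exact permutation p of the list score was 0.108 (0.469 adjusted). The mean log2 deviation of these genes was 0.73 in control library 4 and 0.80 in control library 5, the libraries with the largest share of mitochondrial ribosomal RNA, and lay between -0.44 and 0.25 in the other 10. The difference of the group means was -0.03 among the libraries with Y-linked reads and -0.75 among those without, so that the shift did not hold within the first set. Without control libraries 4 and 5 the median was -0.12 (camera adjusted p = 0.0016 at the preset correlation, with no estimated correlation run there).

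**Figure D3:**
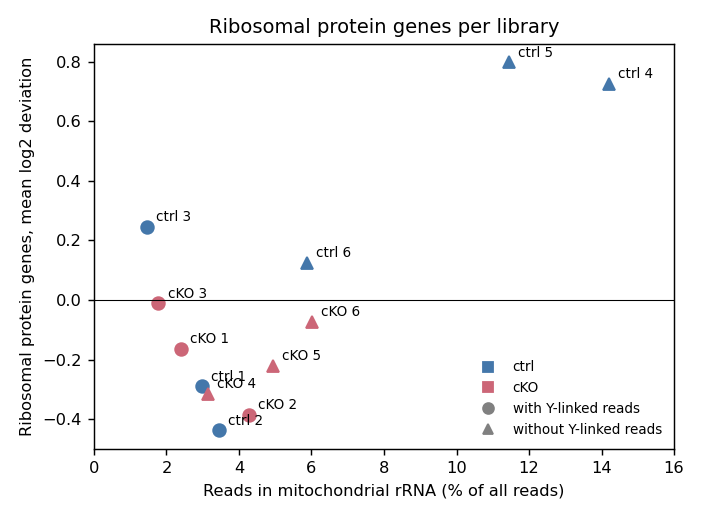
Mean log2 deviation of the 43 ribosomal protein genes in each library against the share of its reads in mitochondrial ribosomal RNA. Control libraries 4 and 5, at 14.2% and 11.5%, stand apart from the other 10 libraries on both axes.

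Marker lists of cell types and regions had medians between -0.09 and 0.05, and camera called none of them with all 12 libraries. The medians were 0.03 for upper-layer and -0.03 for deep-layer excitatory neurons, 0.01 for GABAergic interneurons, -0.07 for astrocytes, -0.03 for oligodendrocytes, -0.04 for their precursors, -0.05 for microglia and -0.02 for vascular and meningeal cells. They were -0.06 for choroid plexus and ependyma, 0.05 for striatum, -0.09 for hippocampus and -0.05 for progenitors and cell cycle. With single libraries left out, medians ran from -0.03 to 0.09 for upper-layer and -0.05 to 0.03 for deep-layer neurons. The ranges were -0.05 to 0.06 for interneurons and -0.09 to 0.12 for striatum. The sign also changed for oligodendrocytes, their precursors, microglia and progenitors. It held for astrocytes (-0.14 to -0.02), vascular cells, choroid plexus and hippocampus. The means of the choroid plexus and hippocampus lists had the opposite sign to their medians, at 0.09 and 0.03, and camera gave the direction of the mean for the first and of the median for the second. Glutamate receptors and scaffolds had a median of 0.01, potassium channels 0.08 and interferon response genes -0.09. Camera called the oligodendrocyte list lower without control libraries 4 and 5 (adjusted p = 0.0177), without cKO library 3 (0.0283) and with array weights (0.0358), and the astrocyte list lower without cKO library 3 (0.0283). It called potassium channels higher without control library 2 (adjusted p = 0.0452) and without cKO library 3 (0.0283). These calls rest on the preset correlation: with all libraries the adjusted p of each of these 3 lists was 0.943 with an estimated correlation. The differences of the mean log2 values had opposite signs in the libraries with and without Y-linked reads for striatum (0.45 and -0.37), astrocytes (0.15 and -0.25), microglia (0.10 and -0.23), progenitors (0.13 and -0.20), choroid plexus (0.25 and -0.07), oligodendrocyte precursors (0.02 and -0.14), vascular cells (0.03 and -0.10), deep-layer neurons (-0.08 and 0.06) and hippocampus (0.08 and -0.01). These differences between the sets were not tested. Single members were called within 3 of these lists, over all genes and adjusted over the list alone. Scnn1a, in the upper-layer list, was described above. Aqp4, the water channel of astrocyte endfeet, rose from 2109 ± 297 to 3035 ± 284 normalised reads (SD, n = 6 each; log2 fold change 0.53, limma adjusted p = 0.00973). Lct, the lactase gene and a member of the hippocampus list, rose by 1.24 on the log2 scale (limma adjusted p = 0.00149), while the median of that list was below 0. Adjusted over the list alone, the calls also took in Klk6 among oligodendrocyte genes (log2 fold change -0.96, limma adjusted p = 0.0166, and 0.0694 over all genes). Prlr and Sostdc1 among choroid plexus genes were called in the same way, with log2 fold changes of 1.01 and 0.93 (both limma adjusted p = 0.0266 over the list, and 0.288 and 0.321 over all genes).

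**Figure D4:**
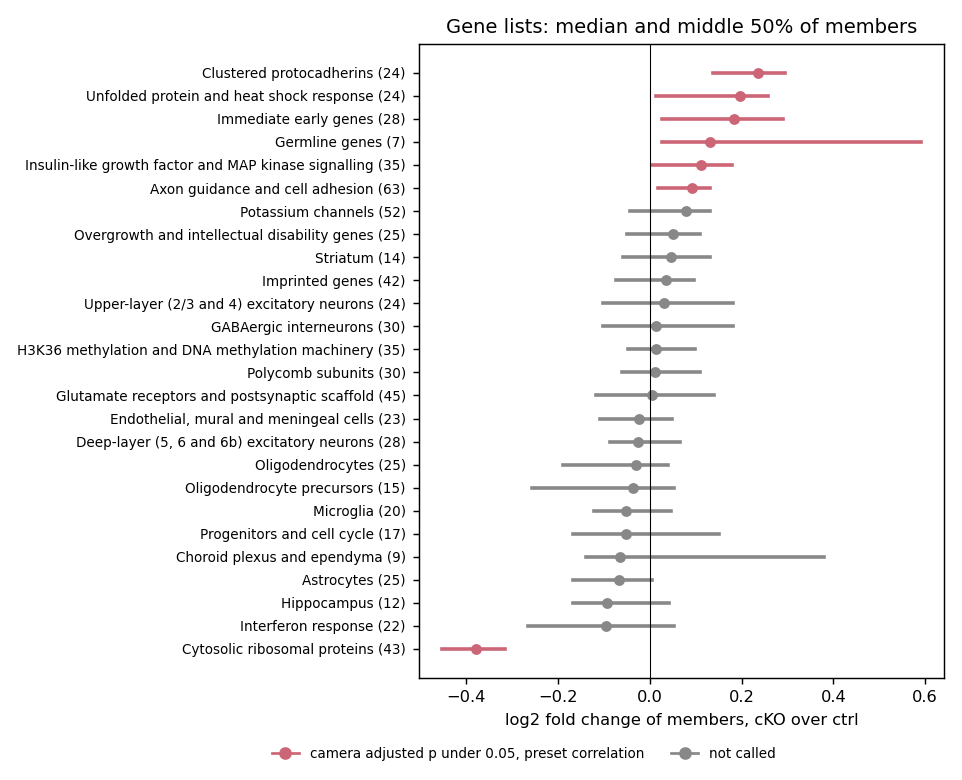
Median log2 fold change of the members of each of the 26 tested lists (point) and the range of the middle 50% of members (line), with the number of tested members in parentheses. Coloured lists had a camera adjusted p under 0.05 with the preset correlation, and none was called with an estimated correlation.

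The genotype effect was next taken within the 3 control and 3 cKO libraries with Y-linked reads and within the 3 and 3 without. Stat6, a transcription factor of cytokine signalling, rose by 1.17 on the log2 scale in the first set (limma adjusted p = 0.000476) and by 1.29 in the second (0.000161), and Esam by 1.24 and 1.33. Stat6 was named after its values were seen. Limma called 36 genes in the libraries with Y-linked reads, 33 higher and 3 lower (Ighg2c, Trim71 and Krt80, a keratin named after its values were seen), and 71 in those without, 56 higher and 15 lower. The lists shared 22 of the genes that rose and 2 of those that fell, where independent lists would share 0.128 and 0.0031. Both effects used the same estimate of the spread of each gene, so the lists were not independent and these expectations may be too low. None of the 3 lower calls with Y-linked reads held without control library 1 or 2 or cKO library 1 or 3. The balance of directions without Y-linked reads depended on the setting: DESeq2 gave 248 higher and 347 lower, and limma without control library 6 gave 432 higher and 658 lower. The test of the difference between the sets called 0 genes in limma, and edgeR also called 0. In limma 1263 genes had an unadjusted p under 0.05, where a share of 0.05 of the tested genes is expected without any difference. DESeq2 called 3, Gm2792, Tmem181b-ps and Lrrc10b, chosen after their values were seen, with log2 differences of 1.68, 1.79 and 2.14 (DESeq2 adjusted p = 0.0330, 0.0207 and 0.0035). On simulated data the limma test recovered 37.3% of genes whose effect differed 2-fold and 81.8% of those whose effect differed 3-fold, so many differences of 2-fold would be missed. Leaving out a single library moved the count with Y-linked reads to between 13 (without cKO 2) and 42 (without cKO 4), and that without Y-linked reads to between 26 (without control 4) and 1090 (without control 6). The latter was 4 without control libraries 4 and 5 together (Kank4, Ces5a, Casp1 and Gadl1, the last named after its values were seen), which leaves a single control there.

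Between the libraries with and without Y-linked reads, limma called 11 genes. Ddx3y, Eif2s3y, Kdm5d and Uty on the Y chromosome were higher in the first set by 7.71 to 9.82 on the log2 scale, which follows from how the sets were defined. Xist, the RNA that silences an X chromosome, differed by -12.31, and Kdm6a and Eif2s3x, X-linked genes known to escape silencing, by -0.52 and -0.68. Without Y-linked reads, Xist was 15020.5 and 11391 normalised reads in control libraries 4 and 5, and 5391 to 5997 in the rest. Nptx2, a secreted synaptic protein, was higher in the libraries with Y-linked reads by 0.85 (limma adjusted p = 0.00292), and Apold1, an endothelial early response gene, had a log2 difference of -1.09 (limma adjusted p = 0.0106). Nptx2 and Apold1 were named after their values were seen. The remaining calls were 5530601H04Rik (-0.82) and G530011O06Rik (1.78).

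Gene length was examined because long genes have been described as sensitive to the loss of DNA methylation outside CG sites in neurons. Across genes, which are not independent replicates, the log2 fold change had a Spearman correlation of 0.24 with genomic span. The 2208 genes of at least 100 kb had a median log2 fold change of 0.03, against -0.01 for the other genes with a known span. Per library, the difference of the medians was -0.02 ± 0.12 in the controls and 0.02 ± 0.08 in the cKO (SD, n = 6 each; exact permutation test, two-sided, p = 0.558). Of 108 genes that rose and had a span, 15 reached 100 kb, or 13.9% against 15.7% of all genes (Fisher's exact test, p = 0.691).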

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

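The test of the ribosomal protein genes without control libraries 4 and 5 was chosen after the result had been seen. The thinned-read and transcript length settings were added after the data had been examined. A library stood apart from the other 5 of its group in 6 of 110 groups of values searched, where chance gives about 5.5. Aqp4 was 2678 normalised reads in control library 4, with 1818 to 2107 in the other controls. Lct was 48.5 normalised reads in control library 1, against 18.2 to 29.2 in the other controls, and 46.3 in cKO library 4, against 66.8 to 75.9 in the other cKO libraries. Pmaip1 was 37.0 normalised reads in cKO library 6 and 17.8 to 23.1 in the others of that group. The mean log2 deviation of the germline list was -0.27 in cKO library 6, with 0.16 to 0.37 in the others, and that of oligodendrocyte precursor genes was -0.28 in cKO library 4, with -0.03 to 0.06 in the others.

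Most called genes were higher in the cKO. With all libraries thinned to equal numbers of reads outside mitochondrial ribosomal RNA, 89.7% of edgeR calls were higher, which argues against fewer reads in the controls as the source, and the lower of the shares under TMM and quantile scaling was 89.7%, which argues against scaling. Of 100 splits of the 12 libraries, 2 gave as many calls, the real split with 120 included, and the highest other gave 1183. A count as large was rare among these splits, which makes chance an unlikely source of it without excluding it. The other split points to a structure of the samples, and the splits counted all calls, not the share that was higher. The design holds 0 libraries with Cre and an intact Nsd1 gene, so an effect of the Cre transgene and one of the loss of Nsd1 cannot be told apart. A biological response to the deletion therefore stays open with the effect of Cre.

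Ribosomal protein genes had a median log2 fold change of -0.38, with no member called. The list was not called with an estimated correlation (camera adjusted p = 0.733). The group means differed by -0.03 among the libraries with Y-linked reads. Without control libraries 4 and 5 the median was -0.12 (camera adjusted p = 0.0016 at the preset correlation, with no estimated correlation run there). Those libraries held the highest scores of the list, so leaving them out shrinks the difference whatever its cause. A difference of those libraries remains a candidate explanation for most of the shift, and its cause was not tested. After removal of the transcript length trend the median was -0.28, between the bounds set for this test, so a length trend may account for part of it and stays open. Whether a shift remains beyond these is not settled, and an effect of the deletion on it stays open too.

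Nsd1 itself was lower by a ratio of 0.768 over the whole gene. It did not pass the limma threshold over all tested genes, while its unadjusted limma p was 0.0099. A control library with a wrong label is argued against, because over the genes called without it each control lay near the control mean, the highest at 0.186 on a scale from 0 at the control mean to 1 at the cKO mean. Removal of the transcript length trend lowered the SD of log2 Nsd1 over the controls from 0.30 to 0.19, a ratio of 0.629, between the bounds set for this test, so the trend may account for part of the spread of the controls. Under that correction the log2 fold change moved from -0.36 to -0.49 and passed the limma threshold. Reads from outside the deleted part of the gene could not be separated and remain an untested explanation.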

How the results depend on the processing

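The settings without control libraries 4 and 5, on thinned reads and with the transcript length trend removed were added after the data had been seen. No single gene or list past its threshold changed direction under the alternatives run. The count of 120 changed genes became 58 with a mean of at least 50 normalised reads, where fewer genes are tested, and 183 with DESeq2 (158 higher, 25 lower); it was 94 to 168 under the other settings. In the libraries with Y-linked reads the 36 calls became 23 without a filter, 18 with a mean of at least 50, 73 with DESeq2, 261 with array weights and 19 with edgeR on thinned reads. In those without Y-linked reads the 71 calls (56 higher, 15 lower) became 534 at an adjusted p under 0.1 (223 higher, 311 lower), 26 with a mean of at least 50, 595 with DESeq2 (248 higher, 347 lower), 5960 with array weights (2949 higher, 3011 lower) and 4 without control libraries 4 and 5. The difference between these effects gave 0 calls in limma and edgeR (1263 and 1239 at an unadjusted p under 0.05), 3 with DESeq2 (1329) and 4667 with array weights. Between libraries with and without Y-linked reads the 11 calls became 20 at an adjusted p under 0.1, 58 with DESeq2 and 57 with array weights. The array weights of the 4-group fit, behind the counts of 261, 5960 and 4667, gave 1 convergence warning, so these counts carry little weight. Those of the main fit, behind the 57, gave 0 such warnings. Nsd1 was called at -0.49 with the transcript length trend removed (limma adjusted p = 0.0041), and its adjusted p ranged from 0.0041 to 0.993 over 26 alternatives. The 7 called lists became 0 with an estimated correlation and 0 with fry. Apart from the settings whose construction shows it, the cause was not tested. Leaving out each library in turn gave 97 to 123 changed genes, 13 to 42 in the libraries with Y-linked reads, 26 to 1090 in those without, 0 to 7 for the difference, where 7 came without control library 6, and 9 to 19 between the sets, where 19 came without cKO library 3. It gave 5 to 10 lists, a log2 fold change of Nsd1 from -0.45 to -0.29 and a length difference of 0.0014 to 0.063. In the libraries with Y-linked reads the count was 16 without control library 1, 22 without control 2, 17 without cKO 1 and 15 without cKO 3. None of these counts held a lower call. In those without, it was 495 without control library 3 (220 higher, 275 lower), 32 without control 5, 46 without cKO 1, 40 without cKO 2, 34 without cKO 4 and 117 without cKO 6 (45 higher, 72 lower), and the 1090 without control library 6 were 432 higher and 658 lower. Same-numbered libraries shared deviations with correlations of 0.34, 0.50, 0.35, 0.095, 0.091 and 0.26, and 7 of 12 correlated best with their own number, a hint from the data that numbers share something. These deviations, from the genotype means, still hold the difference between libraries with and without Y-linked reads; from the means of the 4 groups the correlations were 0.20, 0.46, 0.48, 0.045, -0.098 and 0.034. Not every pair exceeded 0.1 and the numbers were not used as a pairing. With the replicate block, 118 genes (110 shared with the 120), 7 lists and 1 gene for the difference (Lrrc10b, named after its values were seen) were called, Nsd1 had a limma adjusted p of 0.0926 and Cyb5r1 lost its call (0.0739). Over all named genes, lists and alternatives, a gene lost its call in 30 cases and a list in 28, and a list gained it in 6. The length difference was -0.021 with the transcript length trend removed (exact permutation p = 0.509), called under none of the settings run for it, and was not run under edgeR, thinned reads, DESeq2, array weights, the replicate block or without the sex term, since its test uses values per library. Depth limits weakly expressed genes, as 3 reads correspond to up to 5.64 normalised reads.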

Other observations

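The tests of weak expression were chosen after the result had been seen. Genes outside the naming rule that limma called as higher in the cKO were chosen here after their values were seen. Ryr1, the calcium release channel of muscle, rose from 135 ± 32.2 to 270 ± 35.0 normalised reads (SD, n = 6 each), and Trim72, a membrane repair protein, from 19.1 ± 5.49 to 54.1 ± 11.1. Pdyn, the precursor of dynorphins, rose from 116 ± 18.4 to 174 ± 16.7 normalised reads, Tph2, an enzyme of serotonin synthesis, from 28.4 ± 9.86 to 68.6 ± 13.4, and Trhr2, a receptor of thyrotropin-releasing hormone, from 29.1 ± 6.33 to 56.4 ± 11.9. Wnt10a rose from 164 ± 42.7 to 305 ± 40.6 normalised reads and Wnt2b, also a secreted Wnt ligand, from 48.8 ± 9.89 to 97.6 ± 5.35. Cdcp1, a membrane glycoprotein, rose from 8.98 ± 3.63 to 49.3 ± 8.67 normalised reads, and Rag1, the recombinase of lymphocyte receptor genes, from 5.70 ± 2.27 to 19.5 ± 6.78. No theme is drawn from these genes.

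Families defined by the letters of gene symbols were scanned to ask whether members of a family rose together. Families were taken from symbols alone, because a list written from the called genes holds them by construction. Over 439 families the smallest Fisher p adjusted over the families was 0.520, for the Stat family with 2 of 7 tested members, so no family stood out. Called genes next to each other on a chromosome made up 2 pairs, Myh3 with Myh2 and Ighg2c with Ighm, where random placements gave a median of 1 (permutation p = 0.263), so called genes were not shown to cluster. The members of each pair come from the same gene family or locus, and whether they share reads was not tested.

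Called genes were weakly expressed more often than other genes, in both directions. Of the 110, 64.5% had a mean over the 12 libraries under 100 normalised reads, against 22.7% of the other tested genes (Fisher's exact test, p = 1.3e-20, odds ratio 6.21). Of the 10 that fell, 6 had such a mean, against 22.6% of the genes not called (Fisher's exact test, p = 0.0121), so weak expression went with being called and is not tied to gains alone. On simulated data, changes of 1.5-, 2- and 3-fold were pooled within each group of expression. Recovery was 62.3% in the lowest group, 96.9% in the middle and 93.9% in the highest, so it was not raised in the lowest. The size of change was not held fixed, and these groups are not the split at 100 normalised reads. Whether the test itself adds to the share of calls among weakly expressed genes therefore stays open.

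Beside the fall of Ighm and Ighg2c, other genes of the B-cell lineage lay near the floor. Cd79a stood at 2.75 ± 1.51 normalised reads in the controls and 1.36 ± 1.64 in the cKO, Cd79b at 4.17 ± 2.06 and 4.18 ± 2.65, and Igj at 1.74 ± 2.87 and 2.41 ± 2.99 (SD, n = 6 each).

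The split of the 12 libraries that gave 1183 calls placed control libraries 1 and 2 and cKO libraries 1, 2, 5 and 6 against the rest. In a principal component analysis, the components that took most variance held 31.6% and 19.6%, and control libraries 4 and 5 lay apart from the rest on the first. On the second, cKO library 4 lay apart, at -49.3 against -4.52 to 12.4 in the other libraries. Of 100 splits, 54 gave as many called lists as the real 7, and the highest other gave 16, so chance is not excluded for the count of lists. For the libraries with Y-linked reads, 1 of 10 splits gave as many calls as the real 36, which is the real split, and the highest other gave 0. For those without, 1 of 10 gave as many as the real 71 and the highest other gave 0, and 10 splits are too few for a share under 0.05. For libraries with against without Y-linked reads, 3 of 100 splits gave as many calls as the real 11, with 966 as the highest other, but these sets were defined by Y-linked reads, which fixes part of the real count, so this says nothing of the other calls. For the difference between the effects, 100 of 100 splits gave at least the real 0, and the highest other gave 296. Every split reaches a count of 0, so this share says nothing about chance.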
